A study of Homo sapiens with 24 samples.

How the data were processed

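Messenger RNA was sequenced in 24 libraries from 2 established human breast cancer cell lines, MCF7 and T47D, which both carry the estrogen receptor. Each line had 4 groups of 3 libraries: control siRNA (siCtrl) or siRNA against GRHL2 (siGRHL2), each with vehicle or 17β-estradiol (E2). Per the labels' protocols, cells were deprived of hormones for 3 days in stripped serum and then received 0.1% ethanol or 10 nM E2 for 24 h. Also per the labels' protocols, the libraries were stranded poly(A) libraries read as 150 bp pairs. The siRNA sequences, their dose and the day of transfection were not given in the sources used here. Nothing stated whether the 3 libraries of a group came from separate cultures, so the p-values measure the spread between these samples, which may be technical.

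The deposited values are raw read counts per Ensembl gene ID, with 1 column per library and no normalization. Per the submitters' processing notes, the authors trimmed reads with cutadapt and Trim Galore, aligned them with STAR to GRCh38 (hg38) and counted them with featureCounts from Subread; no versions were stated. The annotation release, the strand setting and the handling of reads that map to several genes were not given in the sources used here. Counts of near-identical paralogs and of antisense genes are therefore uncertain. Both tables held 60664 gene IDs, of which 60463 matched a symbol table and 201 did not. Coordinates are those of GENCODE release 29 on GRCh38, which held 58396 of the IDs. Every value was a whole number, and totals ran from 28724385 to 37514265 counts per library.

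Differential expression was computed with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Counts were scaled by the trimmed mean of M values (TMM), genes with few reads were removed by edgeR's default filter, and a robust quasi-likelihood model with 1 mean per group was fitted to the 12 libraries of each line. The filter left 16322 genes in MCF7 and 16836 in T47D, which held at least 99.93% of each library's reads. In each line 5 comparisons were made: knockdown under vehicle, knockdown under E2, E2 with siCtrl, E2 with siGRHL2, and the interaction, which is the E2 effect with siGRHL2 minus that with siCtrl. Differences between the lines, MCF7 minus T47D, were tested in 1 model of all 24 libraries and 18516 genes, for the knockdown effect averaged over both treatments and for the E2 effect with siCtrl. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within a comparison, 2-sided. Levels are CPM (counts scaled to library size) with the TMM factors, given as mean ± SD of 3 libraries, and log2 fold changes are the model's, with their standard error (SE). For a gene with at most 3 counts in a compared group, the ratio of CPM is given with its exact 95% Poisson interval in place of the fitted fold change. Intervals cover counting error or the model's error, not unmeasured differences between cultures.

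Before the data were examined, the groups, comparisons, alternatives, 19 gene lists and the rule for naming genes were fixed. The rule names GRHL2, GRHL1, GRHL3, ESR1, FOXA1, GATA3, PGR, TFF1, GREB1 and CDH1 in every comparison. It adds the 8 largest rises and the 8 largest falls for knockdown under E2 and for E2 with siCtrl in each line, and the 5 largest each way for the interactions and line differences. These needed an adjusted p below 0.05, a mean of at least 2 CPM and a named symbol, and in comparisons of 2 groups every library of 1 group above every library of the other. Up to 4 list members with the smallest adjusted p are named. The lists were written from general knowledge: E2-induced genes, E2-repressed genes, estrogen receptor and cofactors, DNA replication, mitosis, epithelial junctions, epithelial regulators and keratins, mesenchymal genes, basal and myoepithelial markers, stromal and haematopoietic markers, interferon response, inflammatory NF-kB targets, unfolded protein and amino acid response, cholesterol synthesis, p53 targets, ribosome biogenesis, hypoxia and glycolysis, mitochondrially encoded mRNAs, and replication-dependent histones. Each was tested with limma's fry, which asks whether a list's genes move on balance in 1 direction and does not compare them with other genes; its p was adjusted over the 19 lists of a comparison. Each list's median was also placed among 10000 random lists of the same size and matched expression. The percentile is given for some lists, since a list can pass the set test without standing out from random lists. Counts of called members are given over all genes tested and adjusted over the list alone. They are out of the members that passed the filter, which a gene can do through only the group where it is high.

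The size of the E2 response was compared between siCtrl and siGRHL2 as the median interaction over genes that rose, and over genes that fell, on average over both siRNAs; the average E2 effect and the interaction are orthogonal in this balanced design. Knockdown under vehicle and under E2 share no libraries, and neither do the lines, so overlaps between these are between separate libraries. Expected overlaps assume independent calls.

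The model was tested on simulated counts with the fitted dispersions, in which 100 genes changed 2-fold and 100 changed 1.5-fold in the siGRHL2 E2 group. For knockdown under E2 in MCF7 (15471 simulated genes tested), 90 of 100 genes changed 2-fold and 76 of 100 changed 1.5-fold were recovered, and 14 unchanged genes were called, a larger share of the calls than the threshold allows on average. In T47D (16323 genes) 95 and 62 of 100 were recovered and 6 unchanged genes were called. For the interaction, 74 and 43 of 100 were recovered in MCF7 with 10 unchanged genes called, and 70 and 26 of 100 in T47D with 6. In both lines these unchanged genes were again a larger share of the calls than the threshold allows on average. For knockdown under vehicle, where nothing was changed, edgeR called 0 genes in either line.

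The alternatives were median-ratio (RLE) size factors, DESeq2 1.42.0, no filter beyond 1 read, a stricter filter of 5 CPM in 3 libraries, replicate number as a block, only the 6 libraries compared, both lines in 1 model, and leaving out each replicate in turn. For the response sizes, genes were also chosen in the other line. After the data were seen, 3 more were added: a correction for a trend on transcript GC content within each library, T47D without both siCtrl libraries numbered 1, and T47D without the pair of libraries that stood apart on the third principal component. Other ways of dividing the libraries into groups were tested on all 10 splits of each 6, and on 100 drawn relabellings for the interactions and 40 for the line differences. The number 100 was set after a shorter run had been seen. No library was left out of the main results. Figures were drawn with matplotlib 3.10.9 and numpy 2.4.6.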

Results

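Gene expression was measured by RNA sequencing in 24 libraries, 12 from MCF7 and 12 from T47D, 2 breast cancer cell lines that grow in response to estrogen. Within each line, cells received a control siRNA or an siRNA against GRHL2, a transcription factor that maintains epithelial genes, and then vehicle or 10 nM E2 for 24 h. Each of the 8 groups had 3 libraries, and every mean, SD and test that follows rests on 3 libraries per group. Totals ran from 28724385 to 37514265 counts in MCF7 and from 30647348 to 36133498 in T47D. Mitochondrial transcripts took 2.98% to 5.89% of the counts in MCF7 and 7.58% to 11.1% in T47D. Pearson correlations of log2 CPM across genes between libraries of a group lay between 0.9868 and 0.9948; genes are not independent replicates. On the title of the series, the question is how GRHL2 takes part in activation and repression of genes by the estrogen receptor.

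GRHL2 (ENSG00000083307, chromosome 8, 101492432 to 101669726) was the target of the siRNA. In MCF7 its level with siCtrl was 293.9 ± 5.37 CPM under vehicle and 385.1 ± 16.1 CPM under E2, and with siGRHL2 it was 188.1 ± 1.11 and 252.2 ± 14.3 CPM. In T47D it was 234.5 ± 6.14 and 298.4 ± 7.72 CPM with siCtrl, and 88.62 ± 6.56 and 150.6 ± 7.02 CPM with siGRHL2. The share of the siCtrl level left in MCF7 was 64.0% under vehicle (95% interval 59.3% to 69.1%) and 65.5% under E2 (60.7% to 70.7%). In T47D 37.8% was left under vehicle (34.5% to 41.4%) and 50.5% under E2 (46.1% to 55.2%). The fall averaged over both treatments was smaller in MCF7 than in T47D by 0.56 on the log2 scale (SE 0.0604, adjusted p 3.53e-07). These are falls in mRNA only, and the protein was not measured. E2 raised GRHL2 mRNA with siCtrl in MCF7 by 0.39 (adjusted p 2.53e-05) and in T47D by 0.35 (adjusted p 0.00106) on the log2 scale.

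Its paralogs also changed with the knockdown. GRHL1 (ENSG00000134317, chromosome 2, 9951693 to 10002277) fell in MCF7 from 37.22 ± 2.78 to 19.32 ± 2.95 CPM under vehicle and from 41.75 ± 1.78 to 29.22 ± 2.66 CPM under E2 (adjusted p 9.54e-06 and 0.00236). In T47D it fell from 67.7 ± 5.81 to 49.61 ± 1.66 CPM under vehicle and from 70.66 ± 2.01 to 50.76 ± 1.73 CPM under E2 (adjusted p 0.000252 and 0.000183). GRHL3 (ENSG00000158055, chromosome 1, 24319322 to 24364482) rose in MCF7 from 2.151 ± 0.153 to 14.82 ± 3.51 CPM under vehicle and from 0.2415 ± 0.103 to 1.795 ± 0.41 CPM under E2 (adjusted p 1.92e-07 and 2.14e-05). In T47D GRHL3 rose from 9.676 ± 0.375 to 29.07 ± 2.49 CPM under vehicle and from 7.17 ± 0.297 to 23.08 ± 4.1 CPM under E2 (adjusted p 3.36e-07 and 2.68e-07). The rise of GRHL3 was larger in MCF7 than in T47D by 1.17 on the log2 scale (adjusted p 0.000306).

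**Figure D1:**
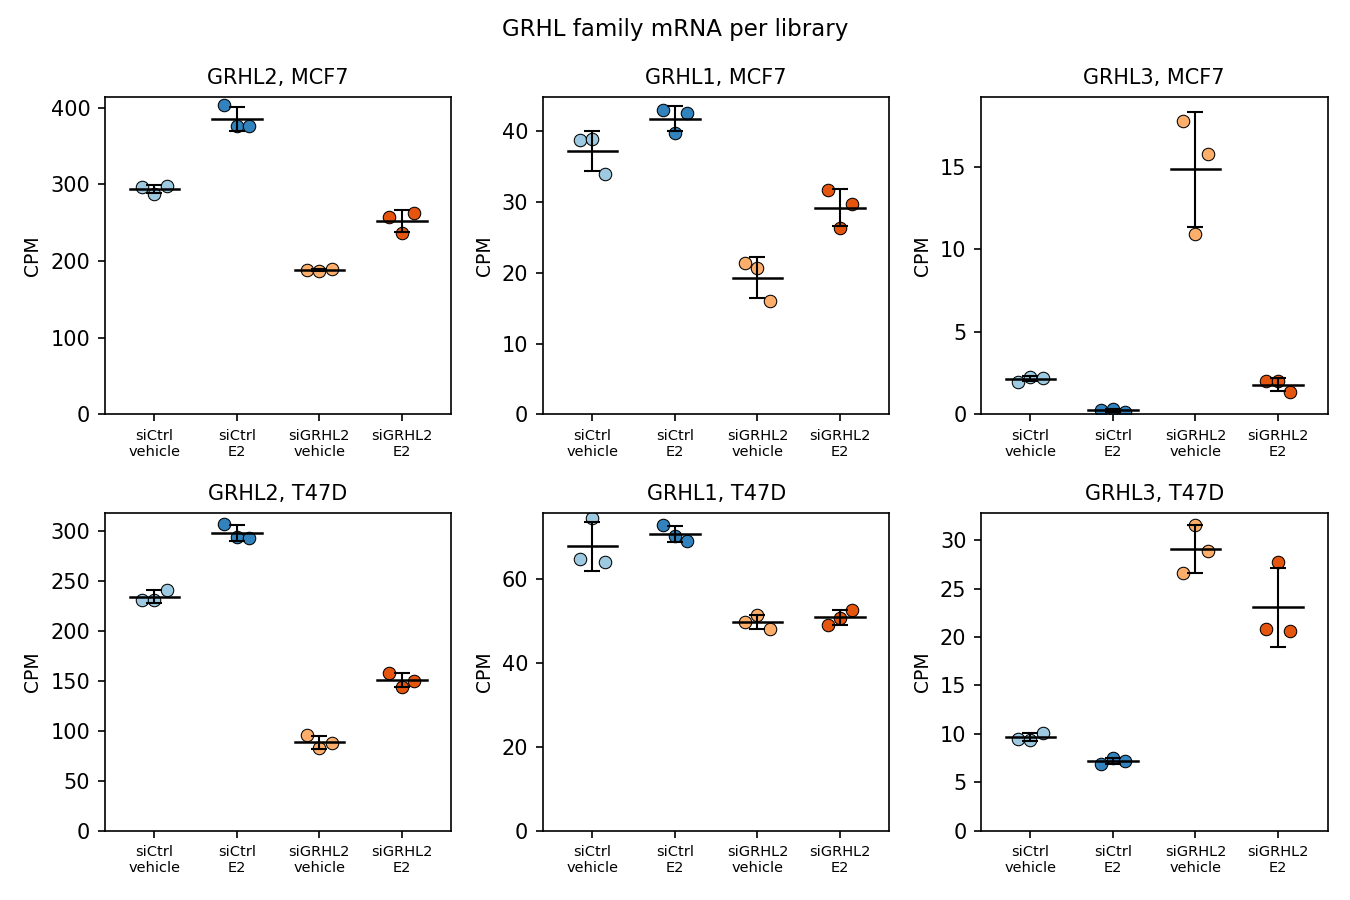
Levels of GRHL2, GRHL1 and GRHL3 in CPM (linear axis) in each library, by line and group; points are libraries and bars the mean ± SD of 3. GRHL2 was lower with siGRHL2 in all 4 pairs of groups, at 188.1 against 293.9 CPM in MCF7 under vehicle and 88.62 against 234.5 CPM in T47D under vehicle, while GRHL3 was higher.

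The knockdown comparisons ask which genes differ between siGRHL2 and siCtrl without and with E2. The labels gave a single siGRHL2 condition and no rescue. Effects of the siRNA on other targets therefore cannot be told apart from loss of GRHL2 in any of these comparisons. In MCF7 under vehicle, 2521 of 16322 genes rose and 3019 fell, of which 672 and 617 changed at least 2-fold. Under E2, 2147 rose and 1998 fell, 452 and 322 of them at least 2-fold. The 2 treatments shared 1331 rises and 1308 falls, where independence would give 332 and 370, and 3.3% of the 2729 genes called in both moved in opposite directions.

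The 8 largest rises with knockdown under E2 in MCF7 follow. PGM5 (ENSG00000154330), a component of cell adhesions, rose from 2.132 ± 0.925 to 20.19 ± 3.69 CPM, a log2 change of 3.22 (SE 0.232, adjusted p 4.8e-07). LOXL2, an enzyme that crosslinks collagen, rose from 4.944 ± 1.15 to 33.11 ± 5.86 CPM. HEG1, a membrane protein of cell junctions, rose from 2.689 ± 0.217 to 20.87 ± 1.14 CPM, and TGFBR2, a receptor of transforming growth factor beta, from 1.484 ± 0.296 to 8.298 ± 0.932 CPM. STC2 (ENSG00000113739, chromosome 5, 173314713 to 173329503), a secreted glycoprotein that E2 induces, rose from 28.34 ± 2.63 to 173 ± 22.8 CPM (log2 change 2.61, SE 0.22, adjusted p 1.91e-06). LINC01016, TBX4 and CYP26B1 made up the rest, with log2 changes of 3.02, 2.78 and 2.64. The largest fall was that of CARD14 (ENSG00000141527), a scaffold of NF-kB signalling in epithelia, from 6.261 ± 0.648 to 0.6201 ± 0.108 CPM, a log2 change of -3.32 (SE 0.242, adjusted p 3.65e-07). NECTIN4, an adhesion molecule, fell from 29.96 ± 0.672 to 5.181 ± 0.996 CPM (adjusted p 1.18e-08), BNIPL from 8.846 ± 0.678 to 1.23 ± 0.153 CPM, and POU2F3, a transcription factor of tuft cells, from 6.35 ± 0.849 to 1.092 ± 0.21 CPM. THEG, PALM3, TRPV3 and MGP had log2 changes of -3.17, -2.999, -2.685 and -2.625.

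The panel genes were tested under both treatments. ESR1 (ENSG00000091831, chromosome 6, 151656691 to 152129619), which codes for the receptor, rose with knockdown in MCF7 by 0.25 under vehicle (adjusted p 0.0261) and by 0.33 under E2 (adjusted p 0.00703) on the log2 scale. FOXA1, a factor that opens chromatin for the receptor, fell by 0.33 under vehicle (adjusted p 0.00284) and rose by 0.28 under E2 (adjusted p 0.0107). PGR and GREB1, classic receptor targets, rose under vehicle from 3.442 ± 1.39 to 6.018 ± 1.95 CPM and from 129.5 ± 45.6 to 218.5 ± 63.8 CPM (adjusted p 0.0271 and 0.0113). No call was made for PGR, GREB1 or TFF1 under E2 (adjusted p 0.7, 0.537 and 0.595) or for GATA3 under either treatment (0.776 and 0.219). CDH1, which codes for E-cadherin, was not called under vehicle (adjusted p 0.987) and rose by 0.30 under E2 (adjusted p 0.0127). Single libraries decided several of these calls: without 1 vehicle library the adjusted p reached 0.0701 for ESR1 (siCtrl replicate 2 or siGRHL2 replicate 3), and 0.158 for PGR and 0.089 for GREB1 (siCtrl replicate 2 or 3, or siGRHL2 replicate 1). Under E2 it was 0.0577 for FOXA1 without siGRHL2 replicate 2 and 0.0688 for CDH1 without siGRHL2 replicate 3.

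Of the 24 mesenchymal genes listed, 14 passed the filter in MCF7. Of these 14, 10 rose and 0 fell with knockdown under vehicle (10 and 0 adjusted over the list alone), and 7 rose and 0 fell under E2 (8 and 1 adjusted over the list alone). The list's medians were 1.42 and 0.98 on the log2 scale (adjusted set-test p 2.87e-05 and 0.000301), and LOXL2, S100A4, FN1 and SNAI2 had the smallest adjusted p under vehicle, with log2 changes of 2.885, 2.602, 1.599 and 2.346. Of the 25 epithelial regulators and keratins, 15 fell and 3 rose under vehicle (16 and 3 adjusted over the list alone; median -0.41, adjusted set-test p 0.000146). Of the members with the smallest adjusted p, the mucin gene MUC1 fell by 1.89, the receptor gene ERBB3 by 1.17 and the motor protein gene MYO5B by 0.80, while MAL2, a gene of apical transport, rose by 0.66. Under E2, 7 fell and 5 rose (8 and 6 adjusted over the list alone), with an adjusted set-test p of 0.207. The 24 epithelial junction genes went both ways, 6 higher and 4 lower under vehicle and 8 higher and 5 lower under E2 (6 and 6, and 10 and 5, adjusted over the list alone; adjusted set-test p 0.0419 and 0.0759). Under vehicle PERP fell by 1.41 and CGN by 0.88 while CXADR rose by 2.11, and with RLE size factors that list's p was 0.133. The junction list's median under vehicle lay at percentile 50.84 of the random lists, so it did not stand out from other genes.

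Cell cycle genes fell in MCF7 under vehicle: 16 of 23 DNA replication genes and 13 of 20 mitosis genes fell and 0 rose (17 and 15 lower adjusted over the list alone). Their medians were -0.39 and -0.51, each with an adjusted set-test p of 0.0326. Among replication genes EXO1 fell by 0.74 and DTL by 0.57, and among mitosis genes HMMR fell by 1.25 and CENPE by 0.94. Under E2, 1 replication gene, MCM3, rose and 0 fell by edgeR (0 and 0 adjusted over the list alone, adjusted set-test p 0.519), while 7 mitosis genes fell and 0 rose (10 lower adjusted over the list alone; median -0.38, adjusted set-test p 0.105). Of 40 E2-induced genes, 16 rose and 7 fell with knockdown under vehicle (17 and 8 adjusted over the list alone; median 0.33, adjusted set-test p 0.0419), led by EGR3, RAPGEFL1, FHL2 and AGR2 with rises of 2.56, 0.97, 2.38 and 0.91. Under E2, 14 rose and 8 fell (14 and 9 adjusted over the list alone; adjusted set-test p 0.0875). Of 15 E2-repressed genes, 7 fell and 4 rose under vehicle (8 and 4 adjusted over the list alone; median -0.41), with log2 changes of -2.0 for BLNK and -1.28 for PIK3IP1. That list's adjusted set-test p was 0.0419, 0.0515 with RLE size factors and 0.0647 with replicate number as a block. Under E2 3 rose and 1 fell (3 and 1 adjusted over the list alone, adjusted set-test p 0.249).

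In T47D under vehicle, 2284 of 16836 genes rose and 2622 fell with knockdown, 429 and 712 of them at least 2-fold. Under E2, 2152 rose and 2407 fell, 363 and 477 at least 2-fold. Both treatments shared 1547 rises and 1893 falls, where independence would give 292 and 375, and 0.174% of the 3446 genes called in both moved in opposite directions. Among the 8 largest rises under E2, NCMAP (ENSG00000184454), a myelin protein gene, rose from 1.078 ± 0.146 to 8.052 ± 0.216 CPM, a log2 change of 2.90 (SE 0.168, adjusted p 4.09e-08). TGFBR3, a coreceptor of transforming growth factor beta, rose from 1.038 ± 0.0222 to 6.237 ± 0.396 CPM. STC1, a secreted glycoprotein, rose from 8.653 ± 0.542 to 34.96 ± 3.93 CPM and the keratin gene KRT13 from 1.213 ± 0.303 to 7.73 ± 3.01 CPM. KCNE4, RNF150, PLEKHH2 and RTL5 rose by 2.78, 2.62, 2.60 and 2.02 on the log2 scale. EPB41L3 (ENSG00000082397), a linker of membrane and cytoskeleton, fell most, from 9.232 ± 1.59 to 0.6629 ± 0.448 CPM, a log2 change of -3.80 (SE 0.337, adjusted p 3.18e-06). ACER1, a ceramidase of the epidermis, fell from 9.174 ± 1.31 to 0.7853 ± 0.0607 CPM, IVL, a gene of squamous differentiation, from 8.41 ± 1.47 to 1.139 ± 0.39 CPM, and CRISP3 from 21.99 ± 1.24 to 3.012 ± 0.229 CPM. ANK1, SLC23A1 and PIK3C2G had log2 changes of -3.11, -2.84 and -2.74; GPC1-AS1 fell by 2.86, but it is an antisense RNA and the strand setting was not given.

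No call was made for ESR1, GREB1 or CDH1 in T47D under either treatment (adjusted p 0.804 and 0.845 for ESR1, 0.106 and 0.836 for GREB1, 0.525 and 0.41 for CDH1). Under E2, FOXA1 rose by 0.33 (adjusted p 0.0026) and PGR by 0.31 (adjusted p 0.0178), although PGR's adjusted p was up to 0.0847 without siCtrl E2 replicate 2 or siGRHL2 E2 replicate 3. TFF1 rose from 3.34 ± 1.03 to 7.49 ± 2.09 CPM under E2 (log2 change 1.16, SE 0.283, adjusted p 0.00752). Under vehicle FOXA1, PGR and TFF1 were not called (adjusted p 0.207, 0.95 and 0.836), and neither was GATA3 under either treatment (0.983 and 0.0811).

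DNA replication and mitosis genes fell together in T47D. With knockdown 22 of 23 replication genes fell under each treatment (22 and 23 adjusted over the list alone) and 19 of 19 mitosis genes fell under each (19 and 19 adjusted over the list alone). Replication medians were -1.26 under vehicle and -0.85 under E2 (adjusted set-test p 0.000182 and 0.000834), and mitosis medians were -1.02 and -0.85 (2.42e-05 and 7.28e-05). Under vehicle the helicase subunit gene MCM4 fell by 1.21, the transcription factor gene E2F2 by 1.51, the survivin gene BIRC5 by 1.76 and the topoisomerase gene TOP2A by 1.27. Epithelial regulators and keratins fell too, 15 lower and 1 higher of 25 under vehicle and 10 and 1 under E2 (16 and 1, and 12 and 1, adjusted over the list alone; adjusted set-test p 0.00166 and 0.0068), with log2 changes of -1.52 and -1.29 for TACSTD2. The 12 mesenchymal genes that passed the filter, of 24 listed, went both ways: under vehicle ITGA5, S100A4 and AXL rose by 1.65, 0.67 and 2.26 and VIM fell by 1.18. Under vehicle 4 of them rose and 1 fell (4 and 1 adjusted over the list alone), and the list's median was -0.072 although its mean was 0.24 and its test direction was up (adjusted set-test p 0.0119). That median lay at percentile 32.39 of the random lists, so it did not stand out from other genes. Under E2 3 rose and 1 fell (3 and 1 adjusted over the list alone; median 0.34, adjusted set-test p 0.00643). Without both siCtrl libraries numbered 1, these p were 0.0908 and 0.0571. Of 14 E2-repressed genes, 3 rose and 5 fell under vehicle (3 and 5 adjusted over the list alone; median -0.19, adjusted set-test p 0.204), and 6 rose and 1 fell under E2 (6 and 1 adjusted over the list alone; median 0.24, adjusted set-test p 0.000671), with IL1R1 rising by 1.17. The 39 E2-induced genes had adjusted set-test p of 0.689 and 0.102, with 6 higher and 10 lower under vehicle and 9 higher and 8 lower under E2 (7 and 10, and 9 and 9, adjusted over the list alone).

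Interferon response genes varied between T47D siCtrl libraries. The mean log2 CPM of 19 such genes was 5.70, 3.99 and 3.58 in the siCtrl vehicle libraries and 4.99, 3.54 and 3.00 in the siCtrl E2 libraries, while the 6 siGRHL2 libraries lay between 2.41 and 2.75. With knockdown 12 of 19 fell under vehicle (17 adjusted over the list alone; median -2.25, adjusted set-test p 0.0548) and 2 of 19 under E2 (0 adjusted over the list alone; median -1.82, adjusted set-test p 0.13). Under vehicle the adjusted set-test p was 0.0498 with RLE size factors and 0.0178 with replicate number as a block (median -1.97). IRF9, OAS3, RIGI and IFIT2 had the smallest adjusted p under vehicle, with log2 changes of -1.52, -2.32, -1.36 and -2.22. Without the siCtrl libraries numbered 1, which had the highest values, 15 and 7 of 19 fell, with medians of -1.37 and -0.92 (adjusted set-test p 0.00398 and 0.0159). In MCF7, 8 fell and 1 rose under vehicle (10 and 1 adjusted over the list alone, median -0.68, adjusted set-test p 0.0658). With replicate number as a block, that p was 0.00123 (median -0.73). Whether the numbers pair samples stays open.

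**Figure D2:**
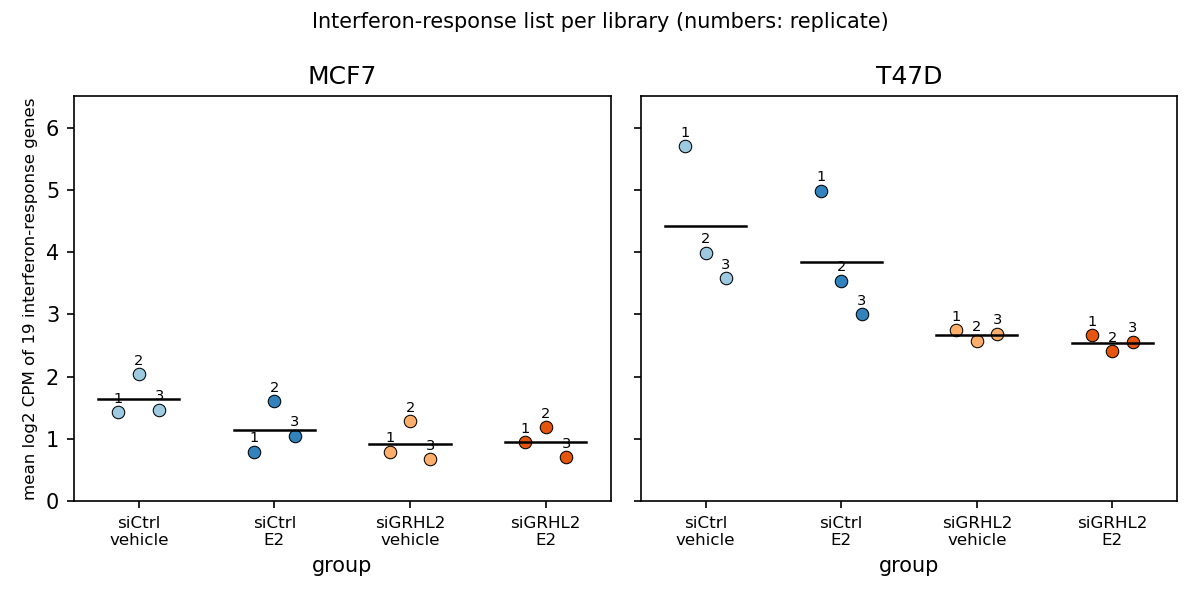
Mean log2 CPM of 19 interferon response genes per library, by line and group; points are libraries with their replicate number and horizontal lines are group means. T47D siCtrl libraries spread from 3.00 to 5.70, and all 6 T47D siGRHL2 libraries lay from 2.41 to 2.75.

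Both lines shared 1124 genes that rose and 1394 that fell with knockdown under vehicle, where independence would give 320 and 449, and 5.9% of the 2676 genes called in both moved in opposite directions. Under E2 they shared 914 rises and 909 falls, against 258 and 277, with 6.08% opposite. The knockdown effect averaged over both treatments differed between the lines for 2965 of 18516 genes, 1563 higher and 1402 lower in MCF7 than in T47D. GRHL2 mRNA itself fell less in MCF7, by 0.56 on the log2 scale. A smaller effect in MCF7 therefore cannot be told apart from a weaker knockdown. LOXL2 differed by 3.53, HEG1 by 3.66, LRP4 by 3.79 and PLEKHG4B by 3.89, each rising in MCF7 relative to T47D (adjusted p 8.47e-05, 7.63e-12, 9.03e-11 and 4.99e-09). ATP6V0A4, a proton pump subunit gene, differed by -3.56 (adjusted p 7.53e-09). LOXL2 and ATP6V0A4 were near 0 in T47D (at most 0.335 and 0.717 CPM in any group). PLEKHG4B had 4 and 9 counts in the MCF7 siCtrl vehicle and E2 groups. The sizes of these differences therefore rest partly on few reads. SPATA18, PPFIA2, MAOB, SLC40A1 and BACH2 also passed, but each had a group with at most 1 count in all 3 libraries, so no fold is given; the call was lost for SPATA18 without T47D siCtrl E2 replicate 3 (adjusted p 1), for BACH2 without MCF7 siCtrl E2 or vehicle replicate 2 (1) and for MAOB in 17 of 24 runs without 1 library (up to 0.0915). ESR1 differed by 0.31 (adjusted p 0.00768) and FOXA1 by -0.26 (adjusted p 0.0151). GREB1 differed by 0.60 and GRHL1 by -0.28, but these calls were lost in 15 and 16 of 24 runs without 1 library, with adjusted p up to 0.0675 and 0.0884. No difference was called for PGR, TFF1, GATA3 or CDH1 (adjusted p 0.351, 0.653, 1 and 0.319). DNA replication genes differed in the same direction, 22 of 23 higher (22 adjusted over the list alone; median 0.88, adjusted set-test p 2.59e-05), which is a smaller fall in MCF7.

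**Figure D3:**
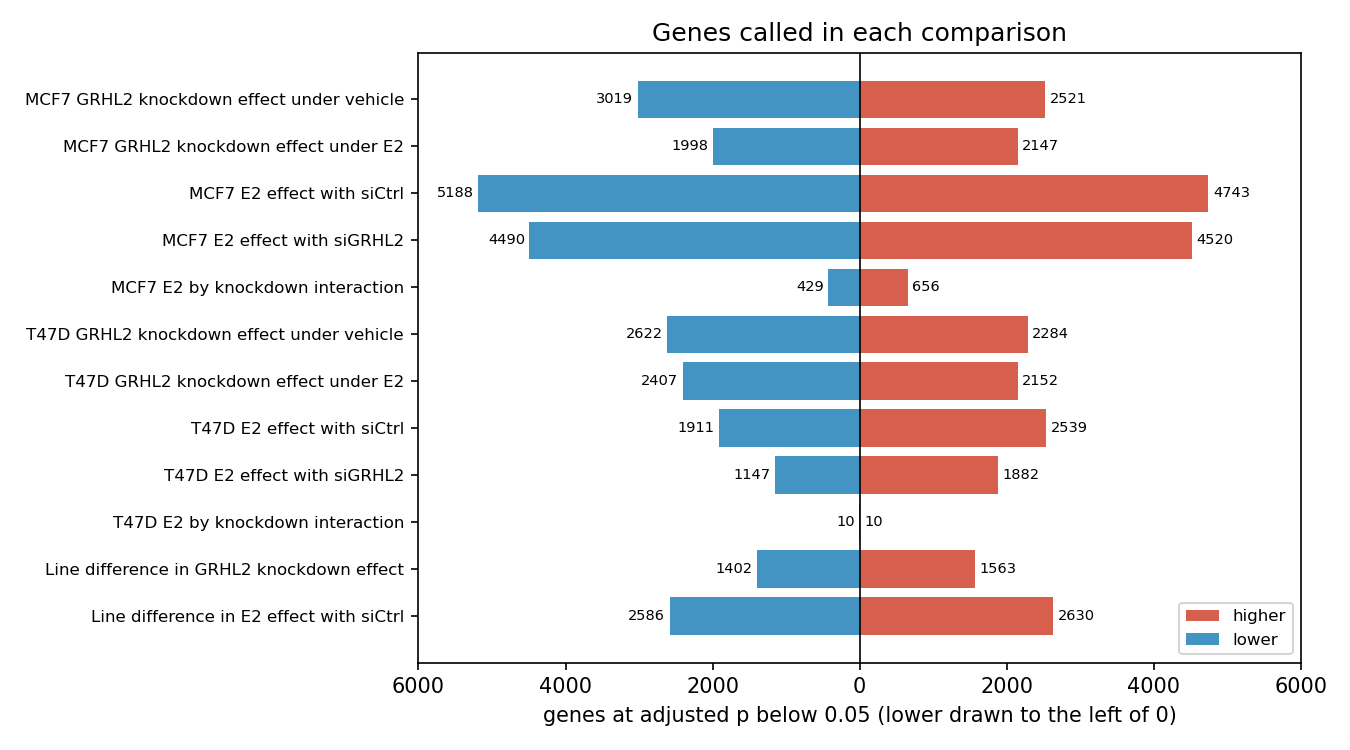
Number of genes higher and lower at an adjusted p below 0.05 in each comparison, by line; bars are counts of genes. E2 with siCtrl called 4743 higher and 5188 lower genes in MCF7 and 2539 and 1911 in T47D, while the T47D interaction called 10 and 10.

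The E2 comparisons give the hormone response with which the knockdown is set. With siCtrl, 4743 of 16322 genes rose and 5188 fell in MCF7, 1597 and 2031 of them at least 2-fold, and with siGRHL2 4520 rose and 4490 fell, 1452 and 1579 at least 2-fold. In T47D 2539 of 16836 genes rose and 1911 fell with siCtrl, 624 and 367 at least 2-fold, and 1882 rose and 1147 fell with siGRHL2, 600 and 200 at least 2-fold. The count of 1147 ran from 723 to 1159 without 1 library, with the lowest without siGRHL2 vehicle replicate 3. It was 1898 without the pair of T47D libraries that stood apart on the third principal component (siCtrl vehicle replicate 2 and siGRHL2 E2 replicate 3), and 2019 after a GC correction, which also took the siCtrl count of 1911 to 2895.

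In MCF7 with siCtrl, E2 raised PGR (ENSG00000082175, chromosome 11, 101029624 to 101130524) from 3.442 ± 1.39 to 256.7 ± 27.9 CPM, a log2 change of 6.21 (SE 0.242, adjusted p 1.34e-10). TFF1 rose from 63.92 ± 15.6 to 1389 ± 145 CPM and GREB1 from 129.5 ± 45.6 to 2231 ± 48 CPM. ESR1 fell from 794.6 ± 109 to 469.8 ± 14 CPM, FOXA1 from 326.3 ± 37.4 to 163.6 ± 3.15 CPM, GATA3 from 1358 ± 137 to 710.2 ± 54.3 CPM and CDH1 from 1682 ± 176 to 1319 ± 44.8 CPM. GRHL3 fell by 3.11 on the log2 scale (adjusted p 9.18e-07) and GRHL1 was not called (adjusted p 0.187). Among the 8 largest rises, the transcription factor gene GATA4 (ENSG00000136574) had 2749 counts with E2 and 1 without, a CPM ratio of 2940 (95% interval 527 to 116000). TUBA3E had 1433 counts against 1, a ratio of 1530 (274 to 60500), and TUBA3D, a near-identical paralog whose reads cannot be told apart with certainty, rose from 0.0381 ± 0.0422 to 30.8 ± 4.02 CPM. The immunoglobulin genes IGHG4 and IGHG3, also near-identical, had 1090 counts against 2 and 433 against 1, ratios of 582 (161 to 4810) and 462 (82.6 to 18300). EGR3, an early growth response factor, rose from 0.3443 ± 0.0887 to 106.6 ± 13.8 CPM, and PGLYRP2 and PDZK1 rose by 7.605 and 7.495 on the log2 scale. WNT2B fell from 180.5 ± 57.8 to 3.797 ± 0.798 CPM and the dopamine receptor gene DRD1 from 96.81 ± 6.03 to 3.401 ± 0.171 CPM. CYP4Z2P, CLEC3A, SLC37A2, MME, TINAGL1 and VAT1L had log2 changes of -6.38, -5.65, -4.80, -4.71, -4.68 and -4.65.

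In T47D with siCtrl, PGR rose from 277.3 ± 13 to 1026 ± 55.4 CPM (log2 change 1.89, SE 0.0925, adjusted p 2.77e-09), GREB1 from 84.61 ± 15.6 to 518.9 ± 20.1 CPM and TFF1 from 0.07973 ± 0.0774 to 3.34 ± 1.03 CPM. ESR1 rose by 0.51 (adjusted p 9.59e-05), while FOXA1 fell by 0.30 (adjusted p 0.00473) and CDH1 by 0.32 (adjusted p 0.00489). GATA3 and GRHL3 fell, with log2 changes of -0.24 and -0.43 (adjusted p 0.0283 and 0.0175), but these calls were lost in 4 and 2 runs without 1 library, with adjusted p up to 0.123 and 0.0614; each was lost without siCtrl E2 replicate 1 or siCtrl vehicle replicate 3, and GATA3 also without siCtrl E2 replicate 3 or siCtrl vehicle replicate 1. GRHL1 was not called (adjusted p 0.575). Among the 8 largest rises, the chemokine gene CXCL12 rose from 7.013 ± 2.27 to 434.2 ± 21.7 CPM and OLFM1, a secreted protein gene, from 8.034 ± 1.48 to 280.9 ± 15.1 CPM. LINC01016 had 620 counts against 3, a CPM ratio of 204 (95% interval 69.5 to 993). SPINK4, ADRA2A, KCNK5, KCNQ5 and NXPH3 rose by 7.18, 5.78, 5.06, 4.92 and 4.80 on the log2 scale. NDRG1, a stress response gene, fell most, from 97.95 ± 23.6 to 21.11 ± 2.81 CPM, and NDP, ABCA1, GRM4, CHRM1, FAM83A, MAF and KCNC1 had log2 changes of -2.07, -2.06, -2.05, -2.03, -1.99, -1.93 and -1.91.

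With siGRHL2 the same panel genes were tested. PGR, GREB1 and TFF1 rose in MCF7 by 5.53, 3.55 and 4.45 and in T47D by 2.19, 2.82 and 6.14 on the log2 scale. In MCF7 ESR1, FOXA1, GATA3 and GRHL3 fell, with log2 changes of -0.68, -0.39, -0.81 and -3.03, and GRHL1 and GRHL2 rose by 0.60 and 0.42, while CDH1 was not called (adjusted p 0.653). In T47D GRHL2 rose by 0.76 and ESR1 by 0.51, while FOXA1, GATA3, CDH1, GRHL1 and GRHL3 were not called (adjusted p 0.404, 0.727, 0.184, 0.818 and 0.0599).

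**Figure D4:**
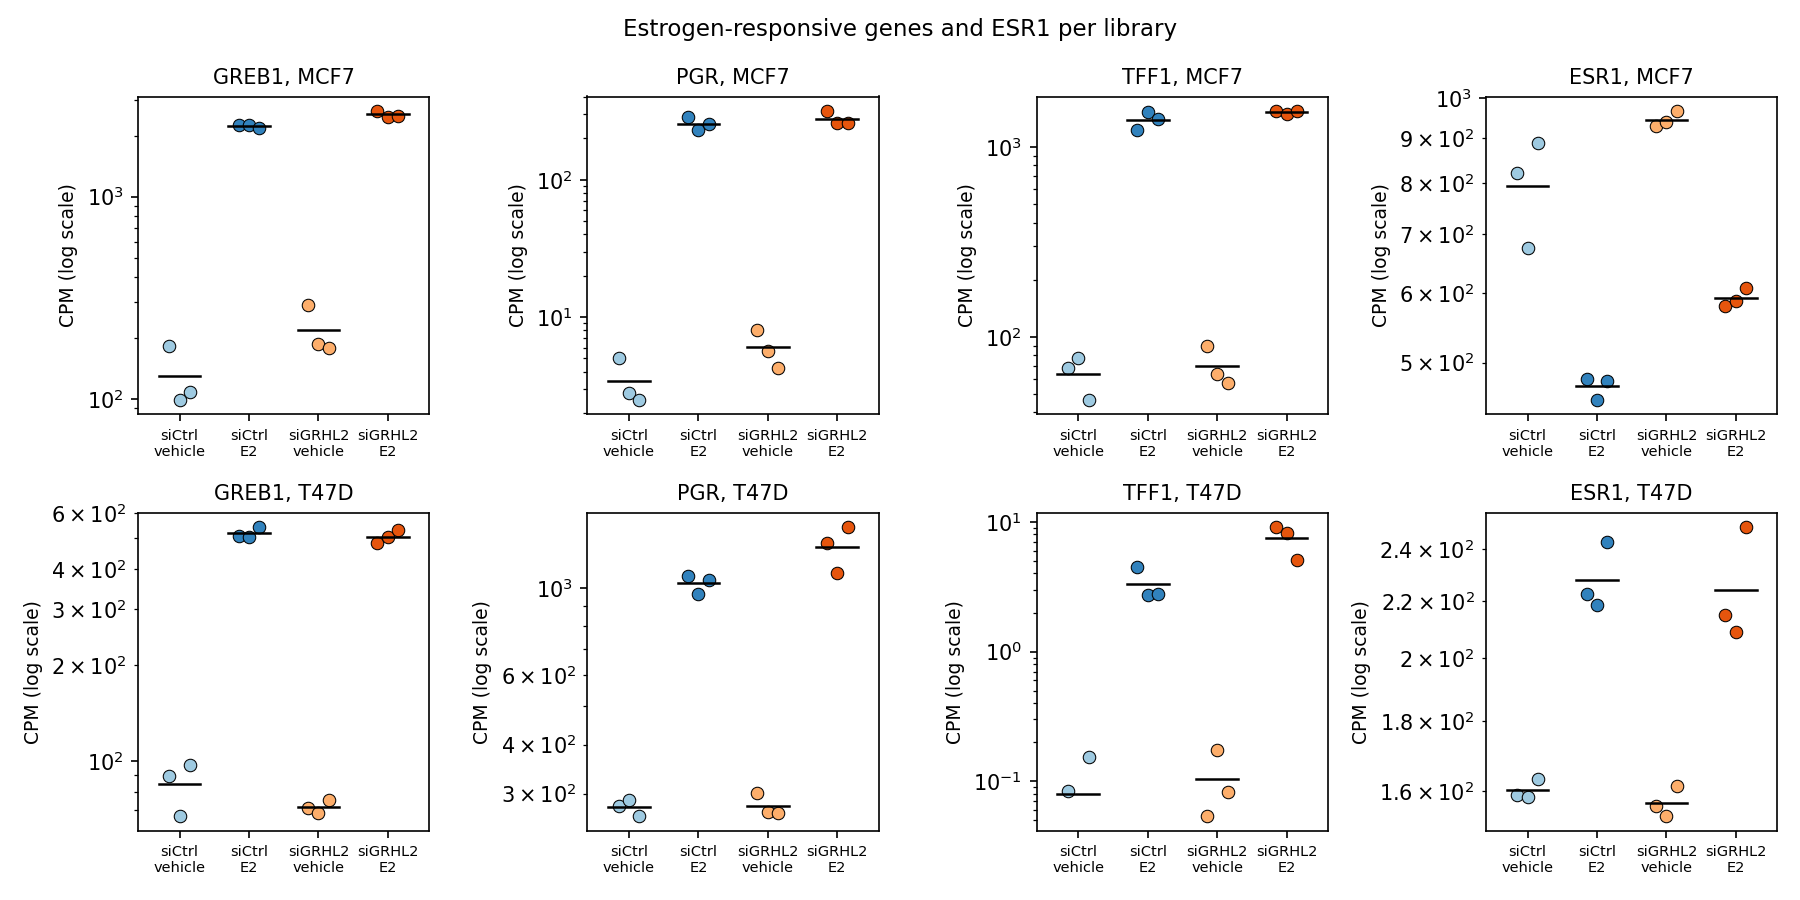
Levels of GREB1, PGR, TFF1 and ESR1 in CPM (log axis) in each library, by line and group; points are libraries and bars the group mean of 3. PGR, GREB1 and TFF1 were higher with E2 under both siRNAs in both lines, and ESR1 was lower with E2 in MCF7 (469.8 against 794.6 CPM with siCtrl) and higher in T47D (228.1 against 160.4 CPM).

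Of the E2-induced genes, 37 of 40 rose in MCF7 with siCtrl and 38 of 40 with siGRHL2, and 39 and 38 of 39 rose in T47D (the same counts adjusted over the list alone; adjusted set-test p 1.54e-08, 1.7e-08, 2.01e-11 and 9.47e-11). Of the E2-repressed genes, 14 and 15 of 15 fell in MCF7 and 13 and 11 of 14 in T47D (the same counts adjusted over the list alone; 3.25e-08, 1.03e-07, 9.3e-09 and 1.02e-07), among them TGFB3, with log2 changes of -3.21 in MCF7 and -0.87 in T47D with siCtrl. All 23 DNA replication genes rose with E2 under both siRNAs in both lines (23 adjusted over the list alone), with medians of 1.5 in MCF7 and 1.28 in T47D with siCtrl and 1.77 in T47D with siGRHL2 (adjusted set-test p 5.71e-07, 2.58e-07, 2.4e-05 and 6.14e-06). All 20 mitosis genes measured in MCF7 and all 19 in T47D rose as well (20 and 19 adjusted over the list alone; medians 2.07 and 2.40, and 1.06 and 1.23). Of 18 ribosome biogenesis genes, 18 and 18 rose in MCF7 and 14 and 10 in T47D (18, 18, 17 and 13 adjusted over the list alone; adjusted set-test p 5.71e-07, 2.7e-06, 8.81e-08 and 8.16e-07), with NOP56 rising by 1.81 and 1.06 with siCtrl in the 2 lines. Epithelial junction genes fell in MCF7, 17 lower and 4 higher of 24 with siCtrl (17 and 4 adjusted over the list alone; adjusted set-test p 3.71e-07), and in T47D 4 fell and 2 rose (4 and 2 adjusted over the list alone; 0.000807). Epithelial regulators and keratins fell in MCF7, 18 lower and 2 higher of 25 (18 and 2 adjusted over the list alone; 2.2e-06), where ERBB3 fell by 1.499.

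**Figure D5:**
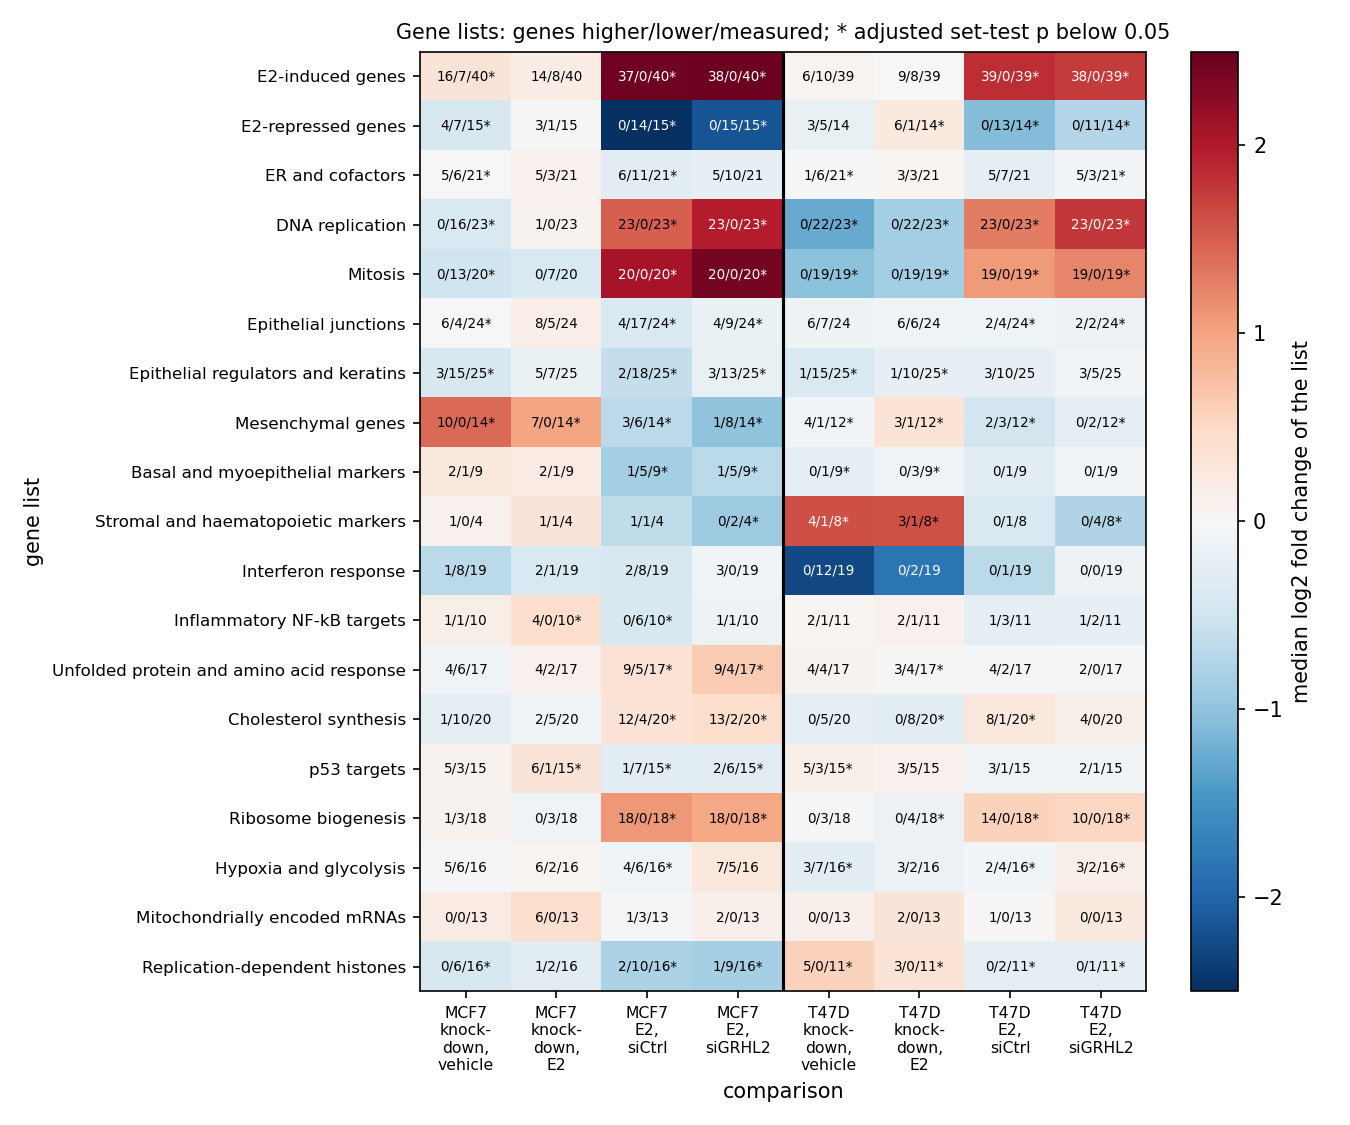
Median log2 fold change of each gene list (colour) in the knockdown and E2 comparisons of each line, with members higher, lower and measured in each cell; a star marks an adjusted set-test p below 0.05. E2-induced, replication and mitosis genes rose with E2 in every column, and replication and mitosis genes fell with knockdown in T47D (medians -1.26 and -1.02 under vehicle).

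The E2 response with siCtrl differed between the lines for 5216 of 18516 genes, 2630 higher and 2586 lower in MCF7. PGR responded more in MCF7 by 4.36 on the log2 scale (SE 0.265, adjusted p 2.08e-10) and GREB1 by 1.53 (adjusted p 0.000191), while ESR1, FOXA1, GATA3 and GRHL3 differed by -1.23, -0.66, -0.66 and -2.64 (adjusted p 9.22e-09, 2.11e-05, 0.000218 and 1.71e-06). PGLYRP2, PNPLA3 and NR5A2 differed by 4.89, 4.85 and 4.76, and RIPOR3, CYP4Z2P and WNT2B by -5.59, -5.40 and -5.01. In MCF7 with siCtrl, PGLYRP2, PNPLA3 and NR5A2 had 7, 11 and 15 counts under vehicle, and CYP4Z2P had 8 under E2. WNT2B was at most 0.59 CPM in the T47D siCtrl groups. The sizes of the differences of these 5 genes are therefore uncertain. RAC2, EGR3, IL1R1 and LINC01671 also passed, but each had a group with at most 2 counts in all 3 libraries, so no fold is given, and the EGR3 call was lost without T47D siCtrl vehicle replicate 1 or 3 (adjusted p up to 0.154). No difference was called for TFF1, CDH1, GRHL1 or GRHL2 (adjusted p 0.578, 1, 0.484 and 0.563). The lines shared 1884 rises and 1243 falls, where independence would give 708 and 520, and 6.8% of 3355 genes called in both moved in opposite directions.

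The interaction asks whether the E2 response itself differs between siCtrl and siGRHL2. Responses keep their sign, so a higher response of a gene that E2 lowers is a smaller fall or a rise. In MCF7, 656 genes had a higher and 429 a lower log2 response with siGRHL2 than with siCtrl. Those counts ran from 328 to 788 and from 277 to 461 without 1 library, lowest without siGRHL2 E2 replicate 3 and without siCtrl E2 replicate 1 and highest without siCtrl vehicle replicate 2, and the second was 723 after a GC correction. FOXA1 was the 1 panel gene called: it fell with E2 by 1.00 with siCtrl and by 0.39 with siGRHL2, a difference of 0.61 (SE 0.103, adjusted p 0.00275). EGR3 rose by 8.25 and by 4.93, a difference of -3.32 (SE 0.243, adjusted p 6.48e-06); its level was 2.076 ± 0.288 CPM with siGRHL2 under vehicle against 0.3443 ± 0.0887 CPM with siCtrl, and 63.24 ± 4.19 against 106.6 ± 13.8 CPM under E2. NKAIN1, a sodium pump partner, rose with E2 from 5.462 ± 1.73 to 9.925 ± 1.32 CPM with siCtrl and from 1.754 ± 0.11 to 19.77 ± 1.45 CPM with siGRHL2. TBX4, a developmental transcription factor, was at 0.673 ± 0.272 CPM with siCtrl and E2 and 4.707 ± 1.38 CPM with siGRHL2 and E2, and MDGA1 at 1.239 ± 0.457 and 6.184 ± 0.0558 CPM. OPN3, an opsin, fell with E2 from 25.02 ± 3.67 to 9.27 ± 1.46 CPM with siCtrl and rose from 6.786 ± 2.14 to 13.47 ± 3.24 CPM with siGRHL2. TGM2, SLC2A3 and PNPLA3 had lower responses, with differences of -2.96, -2.81 and -2.55. For TGM2, SLC2A3 and PDZK1 the mean level with siGRHL2 was not lower under E2, and the larger rise was under vehicle. TGM2 had 95 counts with siCtrl and 975 with siGRHL2 under vehicle, and 1106 and 1447 under E2. PNPLA3 was higher with siGRHL2 under vehicle and lower under E2. LINC01016 (3.41, adjusted p 0.0307) was lost in 5 of 12 runs without 1 library, with an adjusted p up to 0.393, and PDZK1 (-2.71, adjusted p 0.0134) without siCtrl vehicle replicate 3 (0.0635). With siCtrl under vehicle, LINC01016, PNPLA3, PDZK1, EGR3 and SLC2A3 had 7, 11, 19, 36 and 37 counts in all 3 libraries. The sizes of their differences are therefore uncertain. The other panel genes were not called, with adjusted p from 0.111 for GRHL1 to 0.991 for TFF1.

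In T47D the interaction called 10 genes higher and 10 lower, and 1040 genes had an unadjusted p below 0.05. These counts depended on the settings. They were 4 and 7 without both siCtrl libraries numbered 1, 42 and 25 with replicate number as a block, 57 and 40 with DESeq2, 106 and 50 with no low-count filter, 83 and 46 after the GC correction, and 215 and 128 without the pair of libraries apart on the third principal component. Without 1 library they ran from 3 to 26 and from 6 to 16, lowest without siGRHL2 vehicle replicate 2 and without siCtrl E2 replicate 3 and highest without siCtrl vehicle replicate 2. TFAP2C (ENSG00000087510, chromosome 20, 56629302 to 56639283), a transcription factor of mammary epithelium, rose with E2 from 91.51 ± 1.99 to 174.7 ± 4.61 CPM with siCtrl and from 54.31 ± 1.81 to 210.9 ± 16.5 CPM with siGRHL2, a difference of 1.03 (SE 0.094, adjusted p 0.000158). The potassium channel gene KCNH1 rose from 2.921 ± 0.254 to 41.17 ± 1.94 CPM with siCtrl and from 11.92 ± 1.57 to 40.78 ± 1.74 CPM with siGRHL2, a difference of -2.04 (SE 0.148, adjusted p 1.76e-05). RAPGEFL1, an E2-induced gene, reached 135.6 ± 4.09 CPM with siCtrl and 47.93 ± 2.89 CPM with siGRHL2 under E2 (difference -1.44, adjusted p 0.000158). TEX14 and PPP1R3B had higher responses by 1.58 and 1.15, and TMEM229B and MAN1A1 lower ones, with differences of -1.69 and -1.09. OPN3 (0.90, adjusted p 0.0148), RBP7 (-0.95, adjusted p 0.0319) and PLEKHD1 (0.86, adjusted p 0.00737) were lost in 5, 10 and 1 of 12 runs without 1 library, with adjusted p up to 0.0879, 0.153 and 0.0586; siGRHL2 vehicle replicate 2 was the library for PLEKHD1. No panel gene was called, GRHL2 having the smallest adjusted p at 0.147 and ESR1, GRHL1, GRHL3, TFF1 and GREB1 an adjusted p of 1. Of the genes called in both lines, 4 had higher and 5 lower responses in both and 0 went opposite ways. In T47D 37.8% of the siCtrl level of GRHL2 mRNA was left under vehicle and 50.5% under E2. A T47D interaction therefore cannot be told apart from a weaker knockdown under E2.

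Over all 5399 genes that E2 raised in MCF7, the median interaction was -0.035 (set-test p 0.499; from -0.085 without siGRHL2 vehicle replicate 3 to -0.0050 without siCtrl vehicle replicate 3, p at least 0.129), with 214 lower and 186 higher responses called. Over the 5837 genes that E2 lowered it was 0.10 (set-test p 0.0233), with 392 higher and 152 lower responses called, and 64% of these genes had a smaller fall with siGRHL2. The stricter filter took the second value to 0.063 (p 0.0662), and 6 of 12 runs without 1 library had a p above the threshold, up to 0.118. In T47D the median was -0.054 over 3282 raised genes (p 0.129) and 0.11 over 2784 lowered genes (p 0.00612), of which 71.3% had a smaller fall; without siGRHL2 E2 replicate 3 the latter p was 0.054. For the raised genes the p was 0.0088 without the pair of libraries apart on the third principal component, 0.0259 without siCtrl libraries numbered 1 and 0.0398 after the GC correction. Among lists, E2-repressed genes fell less with E2 under siGRHL2 in T47D (median interaction 0.32, adjusted set-test p 0.00458). Their median E2 effect was -1.09 with siCtrl and -0.727 with siGRHL2. By edgeR 0 of 14 interactions were called in either direction (4 higher and 0 lower adjusted over the list alone). The T47D response sizes and this list result cannot be told apart from the weaker knockdown of GRHL2 mRNA under E2. In MCF7 epithelial regulators and keratins fell less on balance (median interaction 0.20, adjusted set-test p 0.0137). Of these 25 genes, 4 had a higher interaction (10 adjusted over the list alone), with MUC1 at 1.63 and ELF3 at 1.43. Their median E2 effect was -0.593 with siCtrl and -0.195 with siGRHL2. The list's median knockdown effect was -0.409 under vehicle and -0.169 under E2 (adjusted set-test p 0.000146 and 0.207). The smaller fall thus went with a lower starting level under vehicle, not with a higher level under E2.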

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

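In this part, the tests of the label swap, of the interferon genes and of the E2-induced genes under vehicle, and the values after the GC correction or without chosen libraries, were chosen only after the result was seen.

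The following effects differed between siRNAs or lines in a test of the difference itself, on the log2 scale. In the MCF7 interaction, signed E2 responses (a smaller fall counts as higher) were higher with siGRHL2 for FOXA1 (0.61), LINC01016 (3.41), TBX4 (2.93), MDGA1 (2.87), NKAIN1 (2.63) and OPN3 (2.41). They were lower for EGR3 (-3.32), TGM2 (-2.96), SLC2A3 (-2.81), PDZK1 (-2.71) and PNPLA3 (-2.55). LINC01016, PNPLA3, PDZK1, EGR3 and SLC2A3 had few reads with siCtrl under vehicle. In the T47D interaction the signed responses were higher for TEX14 (1.58), PPP1R3B (1.15), TFAP2C (1.025), OPN3 (0.90) and PLEKHD1 (0.86), and lower for KCNH1 (-2.04), TMEM229B (-1.69), RAPGEFL1 (-1.44), MAN1A1 (-1.09) and RBP7 (-0.95). These T47D differences cannot be told apart from the weaker knockdown of GRHL2 mRNA under E2. Knockdown effects differed, as MCF7 minus T47D, for GRHL2 (0.56), GRHL1 (-0.28), GRHL3 (1.17), ESR1 (0.31), FOXA1 (-0.26), GREB1 (0.60), PLEKHG4B (3.89), LRP4 (3.79), HEG1 (3.66), LOXL2 (3.53) and ATP6V0A4 (-3.56). A smaller effect in MCF7 cannot be told apart from its weaker knockdown of GRHL2. LOXL2 and ATP6V0A4 were near 0 in T47D, and PLEKHG4B was near 0 in MCF7 with siCtrl. E2 effects differed for GRHL3 (-2.64), ESR1 (-1.23), FOXA1 (-0.66), GATA3 (-0.66), PGR (4.36), GREB1 (1.525), PGLYRP2 (4.89), PNPLA3 (4.85), NR5A2 (4.76), RIPOR3 (-5.59), CYP4Z2P (-5.40) and WNT2B (-5.01). PGLYRP2, PNPLA3, NR5A2 and CYP4Z2P had few reads in an MCF7 group, and WNT2B had few in T47D.

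Among lists, the median interaction differed from 0 by the set test in MCF7 for epithelial junctions (0.18, although 1 member was called higher and 3 lower, 2 and 3 adjusted over the list alone, and the mean was 0.038) and epithelial regulators and keratins (0.20), and in T47D for E2-repressed genes (0.32) and hypoxia and glycolysis (0.16). The junction call was lost with RLE size factors (adjusted p 0.0742) and the hypoxia call without both siCtrl libraries numbered 1 (0.131). For lists and response sizes too, a T47D interaction cannot be told apart from the weaker knockdown of GRHL2 mRNA under E2. Knockdown effects differed between the lines for E2-induced genes (0.31), DNA replication (0.88), mitosis (0.55), epithelial junctions (0.15), mesenchymal genes (0.70), hypoxia and glycolysis (0.14) and replication-dependent histones (-0.65). For lists too, a smaller effect in MCF7 cannot be told apart from its weaker knockdown. Without both T47D siCtrl libraries numbered 1 the mesenchymal and junction calls were lost (0.0539 and 0.0867). E2 effects differed for E2-induced genes (0.58), E2-repressed genes (-1.47), mitosis (1.14), epithelial junctions (-0.16), epithelial regulators and keratins (-0.48), basal and myoepithelial markers (-0.66), p53 targets (-0.19), ribosome biogenesis (0.50) and histones (-0.71). For the estrogen receptor and cofactors the median was 0.0055 while the set test pointed down. Over all genes that E2 lowered (5837 in MCF7 and 2784 in T47D, not the E2-repressed list), the median interaction was 0.10 and 0.11 by the set test. In MCF7 this call was lost with the stricter filter (p 0.0662) and in 6 of 12 runs without 1 library (p up to 0.118), and in T47D without siGRHL2 E2 replicate 3 (0.054). Relabelling could not decide about chance for either.

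Other divisions of the libraries were tried for each count. For each of the 8 comparisons of 3 against 3 libraries, 10 splits are too few for a share under 0.05; the real split was the 1 split with as many genes, at 5540, 4145, 9931 and 9010 genes in MCF7 and 4906, 4559, 4450 and 3029 in T47D for the 2 knockdown and 2 E2 comparisons, and the highest other gave 0 by edgeR. For the interactions and line differences, a relabelling that kept an arm whole carried the real knockdown or E2 effect into the test, and 1 that mixed every arm added that effect to the spread within groups. For the MCF7 interaction 7 of 100 relabellings, the real one included, gave as many as 1085 genes, with a highest other of 2149. The 6 others all kept an arm whole and 0 of 79 that mixed every arm gave as many, so this share decides nothing about chance. For the T47D interaction 4 of 100 gave as many as 20 genes. The highest other, 1194, is many times the real count and points to a structure of the samples: the 3 others all kept an arm whole, and 0 of 79 mixed ones gave as many, so this share, though under 0.05, decides nothing about chance either. The response sizes used the same relabellings, which carry the knockdown effect in the same way, so their shares decide nothing about chance either. A median as far from 0 came from 57 and 6 of 100 for raised and lowered genes in MCF7 (real -0.035 and 0.10, highest other 0.15 and -0.12). In T47D it came from 56 and 16 of 100 (real -0.054 and 0.11, highest other -0.19 and -0.19). Of 79 that mixed every arm, 44 and 2 in MCF7 and 39 and 5 in T47D had a median as far from 0. For the line difference in knockdown 1 of 40 relabellings, the real one, gave 2965 genes, with a highest other of 23; 29 of the others mixed every arm, so this share, though under 0.05, does not by itself exclude chance. For the line difference in E2, 4 of 40 gave 5216 or more, with a highest other of 7716. The 3 others all kept an arm whole, which points to the structure of the samples, and 0 of 32 mixed ones gave as many, so this share too decides nothing about chance.

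A pair of T47D libraries, siCtrl vehicle replicate 2 and siGRHL2 E2 replicate 3, stood apart on the third principal component. Transcript length as a bias of both libraries was excluded, with a correlation across genes of -0.019 in siCtrl vehicle replicate 2. In siGRHL2 E2 replicate 3 it was 0.2, against at most 0.18 in size outside the pair. A length bias in that library alone therefore stays open. A swap of the labels of the pair (median position -0.0298 on a scale from 0 at vehicle to 1 at E2) was excluded. GC content stays open and may contribute: the smaller correlation of the pair was -0.602, beyond the bound written in advance. The next largest in size, 0.598, was that of siGRHL2 E2 replicate 2. Its deviation was taken against a mean that includes replicate 3 of the pair, so it is not a separate comparison. Genes are not independent replicates, and no biological explanation was tested.

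With siGRHL2 in T47D, 12 of 19 interferon genes were called lower under vehicle (17 adjusted over the list alone) and 2 under E2 (0 adjusted over the list alone by edgeR), while the set test of the main fit passed under neither (adjusted p 0.0548 and 0.13). Under vehicle its adjusted p was 0.0498 with RLE size factors and 0.0178 with replicate number as a block. Without the pair apart on the third principal component it was 0.0729, with 9 of 20 members called lower under vehicle and 0 under E2. The siCtrl libraries numbered 1 alone were excluded as the cause, since 15 of 19 members fell under vehicle without them. A response to the control siRNA or its delivery may be the source and cannot be told apart from an effect of GRHL2 on these genes: the siRNA is the group, no untransfected cells were sequenced here, and the SD between siCtrl libraries was 9.74 times that between siGRHL2 libraries. That ratio includes the siCtrl libraries numbered 1, at mean log2 CPM of 5.70 and 4.99 against 3.00 to 3.99 in the other siCtrl libraries.

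E2-induced genes rose on balance with siGRHL2 in MCF7 under vehicle. RNA from E2-treated cells as the whole cause was excluded: 3 genes near 0 in siCtrl vehicle and abundant with E2, GATA4 and TUBA3E among them, allowed a share of at most 0.252%, and 12 of the 16 risen members needed more, EGR3 at least 1.21%; this was the third test tried, after a count of members called lower (7) and a looser bound of 4.34% from list members alone, which 7 of 16 exceeded, under the 8 required. Estrogen left in these cultures cannot be told apart from an effect of GRHL2: the fall of DNA replication genes (16 of 23, median -0.39), which E2 raises, goes against it, with a median of 0.091 for knockdown under E2, but the set test of that difference did not pass (adjusted p 0.0762, 0.0346 with the stricter filter) and in T47D knockdown lowered this list under both treatments. ESR1 and WNT2B, which E2 lowers, rose by 0.25 and 0.71 but did so with knockdown under E2 too (0.33 and 1.93), and TFF1 was not called (adjusted p 0.607). A fall of the E2-repressed list (7 of 15, median -0.41) and of FOXA1 (by 0.33) goes with left estrogen. That list's adjusted set-test p was 0.0419, 0.0515 with RLE size factors and 0.0647 with replicate number as a block. That GRHL2 holds down part of these genes without hormone may also explain the rise, a hypothesis from the same data that was not tested further.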

How the results depend on the processing

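The GC correction and the runs without chosen libraries were chosen only after the result was seen. Each group had 3 libraries of at least 28724385 counts, which leaves genes near the filter poorly measured, and a run without 1 library assumes that the remaining pair varies like the other groups. Why a setting moved a value was not tested.

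The groups of a line carry the same replicate numbers and the same codes in their titles, with the same gaps (1, 3 and 4 in MCF7, 1, 3 and 5 in T47D), but the labels do not state that a number pairs samples. With replicate number as a block, the MCF7 interaction called 655 genes lower and the T47D interaction 42 higher and 25 lower. Correlations between same-numbered libraries were over 0.1 for 9 of 18 pairs in MCF7 (-0.0548 to 0.312) and 13 of 18 in T47D (-0.418 to 0.241), and 9 of 12 libraries in each line correlated best with their own number, so the numbers may mark shared cultures or days, which stays open. Of 228 list results the block took 25 past the threshold and 4 out of it. With it the interferon list passed for knockdown under vehicle in MCF7 (median -0.73, adjusted p 0.00123) and T47D (-1.97, 0.0178), for E2 with siCtrl (-0.45, 0.00172) and the interaction (0.58, 0.0206) in MCF7, and for the line difference in knockdown (1.27, 0.0202). The GC correction gave 723 lower genes for the MCF7 interaction, 2895 and 2019 for the falls with E2 in T47D with siCtrl and siGRHL2, 83 and 46 for the T47D interaction, and -0.057 (p 0.0398) for the response of raised genes in T47D. Without siCtrl libraries numbered 1 the T47D interaction called 4 genes higher and the response of raised genes was -0.066 (p 0.0259). Without the pair apart on the third component, E2 with siGRHL2 called 1898 genes lower, the interaction 215 and 128, the response of raised genes was -0.108 (p 0.0088) and the T47D E2 response size for E2-repressed genes was 0.0771 (p 0.01). DESeq2 gave 57 and 40 and no low-count filter 106 and 50 for the T47D interaction. The stricter filter gave 0.063 (p 0.0662) for the lowered genes in MCF7, and turned the medians of basal markers with knockdown under vehicle to -0.36, and of stromal markers with E2 and siGRHL2 to 0.28 and in the interaction to 0.64, all in MCF7.

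Leaving out each library in turn, counts of genes higher and lower ran from 328 to 788 and 277 to 461 for the MCF7 interaction, from 3 to 26 and 6 to 16 for the T47D interaction, and from 723 to 1159 for falls with E2 and siGRHL2 in T47D. The response of lowered genes ran from 0.053 to 0.13 in MCF7 and from 0.078 to 0.14 in T47D, and that of raised genes from -0.085 to -0.0050 in MCF7 and from -0.0873 to -0.0246 in T47D. Of 171 calls of named genes, 19 were lost in at least 1 such run. Over all these runs of named genes 1962 of 2064 kept their side of the threshold, 93 weakened, 9 passed newly and 0 turned direction. With RLE size factors 223 of 224 and with DESeq2 222 of 224 named results were the same.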

Other observations

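The tests in this part were planned, except those without chosen libraries, which were chosen only after the result was seen. In T47D, 8 of the 19 stromal and haematopoietic markers listed passed the filter. These rose with knockdown, 4 higher and 1 lower of 8 under vehicle and 3 and 1 under E2 (4 and 1 each adjusted over the list alone; medians 1.61 and 1.6, adjusted set-test p 0.000797 and 0.0068; 0.0571 under E2 without siCtrl libraries numbered 1). Of 23 replication-dependent histones listed, 11 passed the filter in T47D and 16 in MCF7. They rose in T47D, 5 and 3 of 11 (6 and 3 adjusted over the list alone; medians 0.58 and 0.35, adjusted set-test p 0.00166 and 0.00141), and fell in MCF7 under vehicle, 6 of 16 (6 adjusted over the list alone; median -0.39, 0.0172). These histone messages mostly lack a poly(A) tail, so the selection of poly(A) RNA limits what their counts mean. Hypoxia and glycolysis genes fell in T47D under vehicle, 7 lower and 3 higher of 16 (7 and 4 adjusted over the list alone; median -0.26, 0.000393). Cholesterol synthesis genes fell in T47D under E2, 8 of 20 (8 adjusted over the list alone; median -0.26, 0.0167), a call lost without siCtrl libraries numbered 1 (0.0571) and without the pair apart on the third component (0.0743). Inflammatory NF-kB targets rose in MCF7 under E2, 4 of the 10 that passed the filter of 18 listed (5 adjusted over the list alone; median 0.42, 0.0182), and p53 targets 6 higher and 1 lower of 15 (6 and 1 adjusted over the list alone; median 0.33, 0.0452; 0.0528 with the stricter filter).

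With E2 and siCtrl in MCF7, cholesterol synthesis genes rose, 12 higher and 4 lower of 20 (12 and 4 adjusted over the list alone; median 0.35, adjusted set-test p 0.00165), and unfolded protein and amino acid response genes 9 and 5 of 17 (9 and 5 adjusted over the list alone; median 0.36, 0.0304; 0.0578 with the stricter filter). The medians of these lists lay at percentiles 97.1 and 96.41 of the random lists. Basal and myoepithelial markers fell, 5 lower and 1 higher of the 9 that passed the filter of 13 listed (5 and 1 adjusted over the list alone; median -0.85, 0.0026). For the estrogen receptor and cofactors 11 fell and 6 rose of 21 (11 and 6 adjusted over the list alone; median -0.29, 0.000616). Mitochondrially encoded mRNAs rose for 6 of 13 with knockdown under E2 in MCF7 (12 adjusted over the list alone; median 0.42, 0.091), without passing the set test.

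Genes moved in opposite directions by knockdown and by E2 made up 58% of the 5318 called for both average effects in MCF7 and 66.1% of 3325 in T47D (each average uses all 12 libraries of its line). In MCF7 1575 were higher with knockdown and lower with E2 and 1509 the reverse, where independence would give 1184 and 1207, against 991 higher and 1243 lower in both, where it would give 1096 and 1305. In T47D these were 974 and 1225 against 563 and 702 expected, and 522 and 604 against 664 and 595. Averaged over treatments, the lines shared 1712 rises and 1907 falls with knockdown and 2426 rises and 1834 falls with E2. Within a line, E2 with siCtrl and with siGRHL2 shared 3806 rises and 3758 falls in MCF7 and 1650 and 874 in T47D.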
